A study of Mus musculus with 12 samples.

How the data were processed

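RNA was measured in 12 libraries of primary lung endothelial cells of wild type C57BL/6J and MLK2 and MLK3 double knockout mice. The cells were kept at 21% oxygen or at 1% oxygen for 90 min. RNA was extracted with the RNeasy Plus kit and libraries were made with the NEBNext Ultra kit, per the labels' protocols. Reads were aligned with TopHat2, per the submitters' processing notes. The authors deposited FPKM values of 52655 transcripts with gene identifiers and symbols. The version of TopHat2, the genome build, the annotation and the tool that made the FPKM values are not given in the sources used here.

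Values of the transcripts of a gene were summed over 23422 gene identifiers. The 11378 genes with a mean of at least 1 FPKM over the 12 libraries were tested on log2(FPKM + 1). Counts were not available, so no count model was used. A linear model with 1 coefficient per group was fitted to all 12 libraries in limma 3.58.1 under R 4.3.3 (8 residual degrees of freedom, moderated variance with a trend on the mean), and p was adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. The comparisons were hypoxia against normoxia in each genotype, double knockout against wild type at each oxygen level, the difference between the hypoxia responses, and their average. The targeted genes were also compared by two-sided exact permutation tests. Positions, lengths and GC content came from GENCODE M21 (GRCm38), which holds 95.4% of the transcript identifiers and positions for 11253 of the tested genes.

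The comparisons, the 40 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The 36 lists with at least 4 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The counts of members past the threshold are given over all genes and, for many lists, also adjusted over the list alone. Where the latter is not given, it can differ from the former. Too few members were tested of the mesothelial list (2), the erythroid and platelet list (2), the sex-linked list (1) and the substrain list (1).

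Named in each comparison were Map3k10 and Map3k11, then the 10 largest positive and 10 largest negative log2 fold changes among genes past the threshold whose library groups did not overlap (5 each way, by adjusted p alone, for the difference and the average). From each list up to 4 members with the smallest p among those past the threshold were added, or up to 2 members with the highest mean FPKM, given as values, where none passed, and predicted or unnamed gene models were passed over. A gene the rule chose for the comparisons of genotypes is not reported here.

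The alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, quantile normalization, equal library medians, the libraries of a comparison alone, a replicate block, no variance trend, array weights, each transcript on its own, camera with an estimated correlation, fry, windows of 5 and 20 Mb, and each library left out in turn. Removal of the trend on GC content and length from each library, and omission of chromosomes 7 and 19, were chosen after seeing the data.

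The FPKM values carry no total counts. Depth was estimated from the steps in low values of 7994 single-transcript genes, taking 275 bases off each transcript, which put 90.0 to 92.8% of low values within 0.1 of a whole fragment. The estimates by group were 24800000, 24500000 and 24700000 fragments in wild type normoxia and 23500000, 22900000 and 26000000 in wild type hypoxia. They were 24400000, 24200000 and 24500000 in double knockout normoxia and 23300000, 21400000 and 22000000 in double knockout hypoxia. Pearson's r of log2 values was 0.9937 to 0.9955 between libraries of a group and 0.9831 to 0.9928 between groups.

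The steps were tested on simulated data with 11378 genes. In the simulated hypoxia comparison in wild type, limma called 43.3%, 86.6% and 97% of genes changed by 0.25, 0.5 and 1 on the log2 scale, and 3.2% of its calls were unchanged genes. In the simulated difference of responses it called 10.4%, 56.7% and 98.5%, and 8.3% of its calls were unchanged genes. For hypoxia in wild type, 39 lists of 30 genes were simulated, of which a single list was changed. That list was called by limma's camera (adjusted p = 5.11e-43), and none of the unchanged lists was. All genes were simulated as independent of each other, so the list test was not checked on genes that vary together.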

Results

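The series looked for pathways that act after the mixed lineage kinases (MLKs) in endothelium. Primary endothelial cells from the lungs of wild type C57BL/6J mice and of mice lacking MLK2 and MLK3 (double knockout) were kept at 21% oxygen (normoxia) or at 1% oxygen for 90 min (hypoxia), with 3 libraries in each of the 4 groups. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so every p measures only the spread between these samples. The libraries held an estimated 21400000 to 26000000 fragments each, with 11281 to 11410 genes at 1 FPKM or more. Fold changes are differences of log2(FPKM + 1), which understates the changes of genes at low levels.

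Map3k10 (ENSMUSG00000040390, GRCm38 chromosome 7, 27656375 to 27674598) encodes MLK2, a kinase upstream of JNK. Its level was 18.9, 18.3 and 19.2 FPKM in the wild type normoxia libraries and 19.1, 16.6 and 16.7 FPKM in the wild type hypoxia libraries. In the double knockout it was 0.145, 0.169 and 0.131 FPKM in normoxia and 1.34, 1.15 and 1.02 FPKM in hypoxia, so the double knockout means were 0.789% and 6.70% of wild type. The transcript that carried most of the wild type signal, at 13.1 to 15.8 FPKM, was listed at 0 in all 6 double knockout libraries. The rest of the double knockout signal came from 1 transcript (ENSMUST00000036453), which was higher in hypoxia than in normoxia by 1.02 FPKM in the double knockout and by 0.990 FPKM in wild type.

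Map3k11 (ENSMUSG00000004054, GRCm38 chromosome 19, 5688742 to 5702865) encodes MLK3, the most studied of these kinases. It was at 36.4, 33.8 and 34.0 FPKM in wild type normoxia and at 32.4, 34.4 and 31.9 FPKM in wild type hypoxia. In the double knockout it was at 11.5, 10.9 and 11.1 FPKM in normoxia and at 12.2, 11.5 and 11.2 FPKM in hypoxia, which is 32.2% and 35.3% of the wild type means. The labels do not say which exons either allele lacks. Map3k9, which encodes MLK1, stayed between 0.328 and 0.455 FPKM in all 12 libraries.

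Over both oxygen levels, Map3k10 averaged 0.659 ± 0.569 FPKM in the double knockout against 18.1 ± 1.19 in wild type (SD, n = 6, two-sided exact permutation p = 0.00217). Map3k11 averaged 11.4 ± 0.455 FPKM against 33.8 ± 1.61 (SD, n = 6, two-sided exact permutation p = 0.00217). That p is the smallest that 6 against 6 libraries allow, and 3 against 3 within an oxygen level cannot go below 0.1. In limma the log2 fold change of Map3k10 was -4.11 in normoxia (adjusted p = 8.25e-12) and -3.09 in hypoxia (adjusted p = 2.33e-10). That of Map3k11 in limma was -1.55 in normoxia (adjusted p = 2.49e-09) and -1.43 in hypoxia (adjusted p = 6.78e-09). Hypoxia did not change Map3k11 past the threshold in wild type (limma log2 fold change -0.08, adjusted p = 0.291) or in the double knockout (0.05, adjusted p = 0.412).

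**Figure D1:**
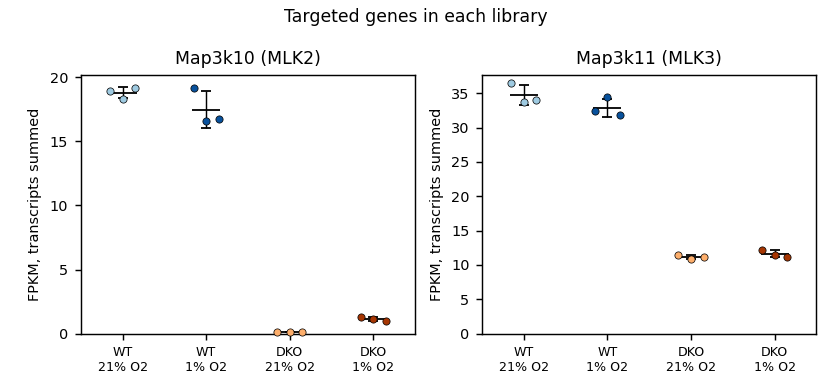
FPKM of Map3k10 and Map3k11, transcripts summed, in each library (points) of the 4 groups, with the mean and SD of 3 libraries. Map3k10 lies between 0.131 and 1.34 FPKM in the 6 double knockout libraries and Map3k11 between 10.9 and 12.2 FPKM.

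Hypoxia of wild type cells raised genes that hypoxia-inducible factors (HIF) drive. Ankrd37, an ankyrin repeat gene and HIF target, rose from 3.22 ± 0.715 to 72.8 ± 4.65 FPKM (SD, n = 3, limma log2 fold change 4.14, adjusted p = 1.39e-09). Bnip3, which marks mitochondria for removal, rose from 12.6 ± 0.745 to 111.2 ± 3.52 FPKM (SD, n = 3, limma log2 fold change 3.05, adjusted p = 8.0e-11). Vegfa, the main endothelial growth factor, rose from 0.615 ± 0.193 to 10.1 ± 2.07 FPKM (SD, n = 3, limma log2 fold change 2.76, adjusted p = 7.87e-07). Among lower genes, Spsb2, an adaptor of ubiquitin ligases, fell from 15.6 ± 0.412 to 6.70 ± 0.911 FPKM (SD, n = 3, limma log2 fold change -1.12, adjusted p = 6.63e-06).

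Ak4, a mitochondrial adenylate kinase, rose from 2.87 ± 0.239 to 56.3 ± 0.532 FPKM (n = 3, log2 fold change 3.89), and Slc16a3, which exports lactate, rose from 1.29 ± 0.197 to 25.6 ± 3.04 FPKM (3.54). Pfkfb3, which speeds glycolysis in sprouting endothelium, rose from 1.86 ± 0.121 to 25.3 ± 4.26 FPKM (3.19). The transcription factor Bhlhe40 rose by 2.18 and the prolyl hydroxylase Egln3, part of the feedback on HIF, by 2.10 on the log2 scale. Kit, a receptor tyrosine kinase, fell from 7.56 ± 0.580 to 3.26 ± 0.448 FPKM (-1.01). Chodl fell by 0.93, Dapk2 by 0.77 and Klhl36 by 0.75 on the log2 scale. A second gene identifier with the symbol Sgsm3 had a lower fitted value than any of these (-1.27, limma adjusted p = 0.0388), but its call was lost in 8 of 14 alternatives. Its call ended without wild type normoxia library 1 or 2 and without wild type hypoxia library 1, 2 or 3 (highest limma adjusted p over the alternatives 0.133). For every gene named here, all 3 hypoxia libraries lay on 1 side of all 3 normoxia libraries.

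Of the 18 tested members of the glycolysis and glucose uptake list, 17 rose in wild type and 1 did not pass (17 higher adjusted over the list alone). Ldha, which turns pyruvate into lactate, rose from 289.3 ± 9.77 to 713.1 ± 21.3 FPKM (SD, n = 3, limma log2 fold change 1.30, adjusted p = 1.48e-09), and Tpi1 from 198.3 ± 2.75 to 505.2 ± 8.62 FPKM. Pdk1 of the same list, which holds pyruvate out of the mitochondria, rose by 1.85 on the log2 scale. Of 40 HIF targets outside glycolysis, 32 rose, none fell and 8 did not pass (34 higher adjusted over the list alone), with Fam162a (1.22) among the higher ones. Both lists were called by limma's camera (adjusted p = 2.70e-28 and 2.08e-33) and kept their calls with an estimated correlation (adjusted p = 0.00587 and 0.00800).

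Of 25 AP-1 and immediate early genes, 14 rose and 11 did not pass (15 higher adjusted over the list alone), among them Ier3, from 120.7 ± 3.19 to 291.6 ± 45.8 FPKM (n = 3), and Junb, from 30.2 ± 1.19 to 64.8 ± 8.75 FPKM. The list was called by limma's camera (adjusted p = 1.16e-06; adjusted p = 0.0902 with an estimated correlation). Of 29 components of the JNK, p38 and ERK pathways, 5 rose, 1 fell and 23 did not pass (5 and 1 adjusted over the list alone). Map2k1, the kinase that activates ERK, rose from 52.7 ± 0.812 to 82.2 ± 1.18 FPKM, Mapk8, which encodes JNK1, from 18.3 ± 1.22 to 23.6 ± 1.13 FPKM, and Map3k4 fell from 8.09 ± 0.355 to 6.15 ± 0.333 FPKM. That list passed in limma's camera (adjusted p = 0.0202; adjusted p = 0.184 with an estimated correlation). MAPK phosphatases did not pass as a list (limma camera adjusted p = 0.259), with 5 of 17 higher, Dusp1 among them (0.43), and Dusp6, a brake on ERK, lower (-0.62).

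Genes of vessel tone and sprouting rose in part. Of 18 vasoactive mediators and receptors, 6 rose and 12 did not pass (6 adjusted over the list alone; limma camera adjusted p = 0.00684; adjusted p = 0.191 with an estimated correlation), with the vasodilator peptide gene Adm (0.34), its receptor Calcrl (0.43) and Ptgs2 (0.89) higher. Of 21 angiogenic receptors and tip cell genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone; limma camera adjusted p = 0.00684; adjusted p = 0.366 with an estimated correlation), Esm1 among the higher ones. Of 18 heat shock genes, 6 rose and 1 fell (8 and 2 adjusted over the list alone; limma camera adjusted p = 0.0178; adjusted p = 0.289 with an estimated correlation), with Hspa1a (0.78) and Hspa1b (0.75) among the higher ones. Of 19 NRF2 antioxidant genes, 9 rose (9 adjusted over the list alone; limma camera adjusted p = 0.00569; adjusted p = 0.142 with an estimated correlation), led by Gclc (0.59), which makes glutathione.

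Of 34 genes of DNA replication and S phase, 16 fell, none rose and 18 did not pass (25 lower adjusted over the list alone), such as Pole, from 27.5 ± 0.178 to 21.9 ± 0.387 FPKM (n = 3). The list was called by limma's camera (adjusted p = 3.25e-08; adjusted p = 0.170 with an estimated correlation). Of 34 mitosis and G2/M genes, 8 fell and 26 did not pass (9 adjusted over the list alone; limma camera adjusted p = 0.00184; adjusted p = 0.490 with an estimated correlation), with Aurkb (-0.34) among them.

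The actin and YAP list had 6 of 24 members higher (limma camera adjusted p = 0.0181; adjusted p = 0.561 with an estimated correlation), Cyr61 (0.52) among them. Pan-endothelial markers had 7 of 32 higher and 2 lower (limma camera adjusted p = 0.0202; adjusted p = 0.381 with an estimated correlation), and lymphatic endothelial markers had 4 of 10 higher (limma camera adjusted p = 0.0178; adjusted p = 0.516 with an estimated correlation), with Prox1 (0.52). Smooth muscle and pericyte markers had 3 of 7 higher (5 adjusted over the list alone; limma camera adjusted p = 0.0278; adjusted p = 0.381 with an estimated correlation). None of 49 ribosomal protein genes passed, although the list was called higher (limma camera adjusted p = 0.00175; adjusted p = 0.601 with an estimated correlation), and 3 of 9 structural RNAs fell (limma camera adjusted p = 0.0181; adjusted p = 0.366 with an estimated correlation). Quantile normalization ended the calls of the heat shock, actin, pan-endothelial and ribosomal lists (limma camera adjusted p = 0.278, 0.227, 0.360 and 0.551). Without a filter on low values the smooth muscle list did not pass (limma camera adjusted p = 0.347), and fry did not call the actin and ribosomal lists (limma adjusted p = 0.0842 and 0.0978). The library means of the lymphatic list overlapped (hypoxia 0.303, 0.339 and 0.062, normoxia -0.094, 0.129 and -0.035, on the log2 scale). Those of the actin list did too (hypoxia 0.179, 0.133 and 0.049, normoxia -0.050, 0.108 and -0.058). In each of these lists the p with an estimated correlation was the highest of the alternatives.

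In wild type, 2370 of 11378 tested genes changed (20.8%; limma adjusted p under 0.05), 1192 higher and 1178 lower, and 45 rose and 4 fell by more than 1 on the log2 scale. Without wild type hypoxia library 1 the count was 1382, and without library 2 it was 1495. Of 36 lists, 16 were called by limma's camera, 2 of them also with an estimated correlation.

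Hypoxia of double knockout cells raised the same leading HIF targets. Ankrd37 rose from 2.83 ± 0.578 to 76.1 ± 6.19 FPKM (SD, n = 3, limma log2 fold change 4.34, adjusted p = 2.01e-09). Bnip3 rose from 12.3 ± 0.949 to 105.3 ± 7.48 FPKM (SD, n = 3, limma log2 fold change 3.00, adjusted p = 9.79e-11). Vegfa rose from 0.625 ± 0.356 to 10.3 ± 0.969 FPKM (SD, n = 3, limma log2 fold change 2.82, adjusted p = 4.84e-07). The stress response gene Nupr1 rose from 47.2 ± 2.36 to 160.2 ± 9.32 FPKM (SD, n = 3, limma log2 fold change 1.74, adjusted p = 2.32e-06). Spsb2 fell from 17.2 ± 1.35 to 5.27 ± 0.464 FPKM (SD, n = 3, limma log2 fold change -1.54, adjusted p = 3.15e-07).

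Pfkfb3 (3.59), Ak4 (3.30), Slc16a3 (2.87), Bhlhe40 (1.78), Egln3 (1.76) and the oestrogen receptor gene Gper1 (1.68) also rose in the double knockout, as log2 fold changes. The pentraxin Ptx3, an inflammatory mediator, fell from 7.08 ± 0.367 to 2.24 ± 0.588 FPKM (SD, n = 3, limma log2 fold change -1.33, adjusted p = 4.24e-05). Klhl36 (-1.29), the Notch glycosyltransferase Lfng (-1.21) and Kit (-1.17) also fell. Oxnad1 had a fitted change of -1.37 (limma adjusted p = 0.0336), but its call ended in 7 of 14 alternatives, among them without double knockout normoxia library 1 or 2 and without double knockout hypoxia library 1, 2 or 3 (highest limma adjusted p over the alternatives 0.135). All 3 hypoxia libraries of every gene named here lay on 1 side of all 3 normoxia libraries. Map3k10 itself rose with hypoxia in the double knockout (limma log2 fold change 0.92, adjusted p = 3.12e-06) and did not pass in wild type (limma log2 fold change -0.10, adjusted p = 0.333), and the difference between the genotypes was 1.02 (limma adjusted p = 0.00375).

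Glycolysis genes rose in 17 of 18 cases in the double knockout (17 adjusted over the list alone), with Ldha from 282.1 ± 11.5 to 701.4 ± 21.7 FPKM (n = 3) and Tpi1 from 206.0 ± 13.6 to 504.5 ± 10.8 FPKM. Pdk1 of the same list rose by 1.61 on the log2 scale. Of 40 HIF targets outside glycolysis, 31 rose, 3 fell and 6 did not pass (34 and 3 adjusted over the list alone), with Fam162a (1.22) among the higher ones. Both lists were called by limma's camera (adjusted p = 3.76e-17 and 8.72e-19) and with an estimated correlation (adjusted p = 0.0319 and 0.0485).

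Of 25 AP-1 and immediate early genes, 13 rose and 6 fell (13 and 6 adjusted over the list alone; limma camera adjusted p = 0.0301; adjusted p = 0.567 with an estimated correlation), with Ier3 (1.53) among the higher ones. Vasoactive genes had 8 of 18 higher and 1 lower (10 and 1 adjusted over the list alone; limma camera adjusted p = 0.00906; adjusted p = 0.278 with an estimated correlation), and Ptgs2 rose from 6.29 ± 0.232 to 18.1 ± 2.06 FPKM (n = 3). Of 18 heat shock genes, 12 rose and 6 did not pass (12 adjusted over the list alone; limma camera adjusted p = 0.000725; adjusted p = 0.154 with an estimated correlation), with Hspa1a from 7.74 ± 0.0290 to 17.6 ± 1.31 FPKM and Hspa1b from 104.9 ± 3.24 to 208.1 ± 13.4 FPKM. Of 29 genes of the unfolded protein and integrated stress responses, 12 rose and 2 fell (12 and 2 adjusted over the list alone; limma camera adjusted p = 0.0296; adjusted p = 0.675 with an estimated correlation), including Atf4 (0.59) and Ppp1r15a (0.52). NRF2 antioxidant genes had 9 of 19 higher (9 adjusted over the list alone; limma camera adjusted p = 0.00812; adjusted p = 0.154 with an estimated correlation), Gclc (0.73) among them.

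In the double knockout 13 of 34 mitosis genes were higher, 1 was lower and 20 did not pass (18 and 1 adjusted over the list alone; limma camera adjusted p = 0.00469; adjusted p = 0.675 with an estimated correlation), such as Cdc20 (0.25) and Prc1 (0.21). S phase genes were not called (limma camera adjusted p = 0.820), with 2 of 34 lower. Actin and YAP genes had 8 of 24 higher (8 adjusted over the list alone; limma camera adjusted p = 0.00444; adjusted p = 0.675 with an estimated correlation). Quantile normalization ended the calls of the AP-1, stress response, NRF2 and actin lists (limma camera adjusted p = 0.0557, 0.268, 0.109 and 0.0670). The list of JNK, p38 and ERK components did not pass in the double knockout (limma camera adjusted p = 0.0918), with 11 of 29 higher and 4 lower, and its difference between genotypes did not pass (adjusted p = 0.922). Other lists did not pass in limma's camera: hypoxia sensing (adjusted p = 0.624; 2 of 10 higher and 3 lower), Notch (adjusted p = 0.820; 4 of 12 higher and 5 lower), cholesterol synthesis (adjusted p = 0.330; 2 of 22 higher and 5 lower) and mitochondrially encoded genes (adjusted p = 0.599; 1 of 11 higher). The median of the Notch members was 0.07 while their mean was -0.09.

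In the double knockout, 4468 genes changed (39.3%; limma adjusted p under 0.05), 2233 higher and 2235 lower, and 41 rose and 17 fell by more than 1 on the log2 scale. Of 36 lists, 9 were called by limma's camera, 2 of them also with an estimated correlation.

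Both genotypes raised 965 genes and lowered 944, against 233.9 and 231.4 if the calls were independent, and 11 genes were called in opposite directions. With 1 library left out, the lowest shared counts were 650 and 544, without wild type hypoxia library 1, against 141.2 and 124.2. The calls in opposite directions then ranged from 2 to 16. The log2 fold changes correlated across the 11378 genes with Pearson r = 0.730 and Spearman rho = 0.712, and 77.3% had the same sign, although genes are not independent replicates. The 2 contrasts share no library. Over genes with a mean of at least 5 FPKM, r was 0.781. The major axis slope of the double knockout response on the wild type response was 1.37, and leaving out 1 library moved it between 1.21 and 1.46. For the 58 members of the HIF and glycolysis lists the slope was 0.968 (0.949 to 0.993), and for the other 11320 genes it was 1.499 (1.29 to 1.61). For the 4319 genes with a mean of at least 20 FPKM it was 1.26.

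**Figure D2:**
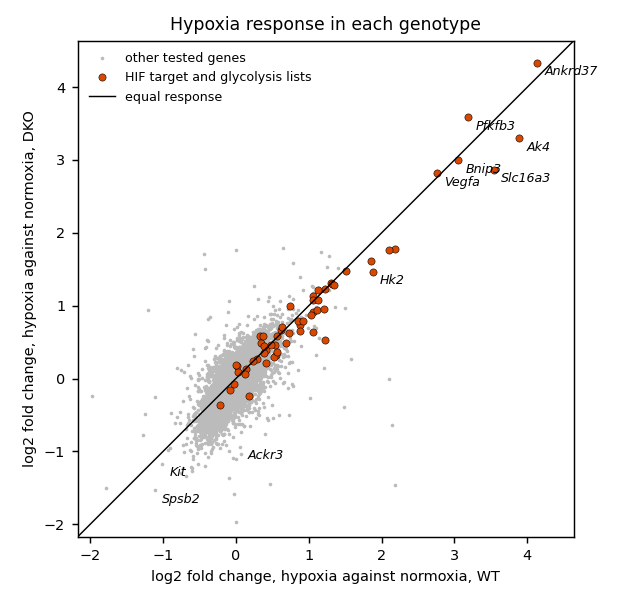
Each point is a tested gene, with the log2 fold change of hypoxia against normoxia in wild type on the x axis and in the double knockout on the y axis, and the line marks an equal response. The 58 members of the HIF and glycolysis lists (orange) lie near the line, with a slope of 0.968.

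Without hypoxia, double knockout cells differed from wild type in genes of several functions. Clca2, a cell adhesion protein induced by p53, was at 46.7 ± 1.77 FPKM in the double knockout and 15.6 ± 1.47 in wild type (SD, n = 3, limma log2 fold change 1.53, adjusted p = 2.55e-08). Lyz2, the lysozyme of myeloid cells, was at 62.1 ± 5.97 against 21.4 ± 4.22 FPKM (SD, n = 3, limma log2 fold change 1.51, adjusted p = 9.99e-06). Apoe, which carries lipids, was at 10.0 ± 0.773 against 34.9 ± 1.37 FPKM (SD, n = 3, limma log2 fold change -1.71, adjusted p = 2.15e-08). Pop4, a subunit of RNase P, was at 4.33 ± 0.752 against 16.5 ± 0.925 FPKM (SD, n = 3, limma log2 fold change -1.72, adjusted p = 7.16e-07). Phgdh, the entry enzyme of serine synthesis that endothelium needs, was at 40.3 ± 2.78 against 67.6 ± 0.304 FPKM (SD, n = 3, limma log2 fold change -0.73, adjusted p = 4.85e-06).

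Blvrb, a biliverdin reductase, was higher in the double knockout at 59.4 ± 1.97 against 20.5 ± 0.758 FPKM (n = 3, log2 fold change 1.49). The capillary lipase anchor Gpihbp1 (1.25), the basement membrane collagen Col15a1 (1.20) and the complement gene C3 (1.17) were also higher. Fhl1 (-1.21), the imprinted RNA H19 (-0.998), the mitochondrial ribosome gene Mrps12 (-0.997) and Zfp93 (-0.99) were lower. Erdr1 was at 8.96, 11.5 and 9.72 FPKM in wild type normoxia and at 13.5, 13.6 and 10.9 in wild type hypoxia, and it was listed at 0 in 5 double knockout libraries and at 0.104 in the third hypoxia library. All 3 double knockout libraries lay on 1 side of all 3 wild type libraries for every gene named here.

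Mitosis genes were lower in the double knockout in normoxia, with 21 of 34 lower, none higher and 13 not past the threshold (30 lower adjusted over the list alone). Prc1 was at 23.4 ± 1.47 against 30.2 ± 0.577 FPKM (n = 3, -0.36), Ube2c, which drives mitotic exit, at 16.5 ± 0.423 against 22.7 ± 0.177 FPKM (-0.44), and Tpx2 at 11.6 ± 0.265 against 14.9 ± 1.03 FPKM (-0.33). The list was called by limma's camera (adjusted p = 1.16e-18; adjusted p = 0.164 with an estimated correlation). S phase genes had 6 of 34 lower and 28 not past the threshold (9 lower adjusted over the list alone; limma camera adjusted p = 7.14e-06; adjusted p = 0.269 with an estimated correlation), with Pold1 (-0.58) among them. Of 20 p53 targets, 4 were higher (5 adjusted over the list alone; limma camera adjusted p = 0.00244; adjusted p = 0.194 with an estimated correlation), among them Cdkn1a (0.33), which halts the cell cycle, and Pmaip1 (0.66).

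Macrophage and other leukocyte markers had 4 of 8 tested members higher and 4 not past the threshold (6 higher adjusted over the list alone; limma camera adjusted p = 1.00e-05; adjusted p = 0.0335 with an estimated correlation). Beside Lyz2, Marco was at 1.99 ± 0.356 against 0.425 ± 0.0490 FPKM (n = 3) and Ctss at 3.44 ± 0.269 against 1.35 ± 0.182 FPKM. Smooth muscle and pericyte markers had 4 of 7 higher in normoxia (4 higher and 2 lower adjusted over the list alone). Camera did not call them while fry did (limma camera adjusted p = 0.0792, 0.528 with an estimated correlation, and fry adjusted p = 0.00883). Their mean on the log2 scale, as the distance from the wild type normoxia mean, was 0.164, 0.262 and 0.206 in the double knockout libraries against -0.003, 0.106 and -0.102 in wild type. The MLK family list was called lower through Map3k10 and Map3k11 (limma camera adjusted p = 0.00174; adjusted p = 0.194 with an estimated correlation), and its other 2 tested members did not pass. Ribosomal protein genes were called higher with 1 of 49 past the threshold (limma camera adjusted p = 0.000334; adjusted p = 0.623 with an estimated correlation), a call that quantile normalization and fry ended (limma adjusted p = 0.132 and 0.181). Their library means overlapped (double knockout -0.007, 0.068 and 0.112, wild type 0.007, -0.039 and 0.032, on the log2 scale). Lists not called by limma's camera included BMP and TGF-beta signalling (adjusted p = 0.965; 6 of 32 higher and 3 lower), NF-kB genes (adjusted p = 0.0836; 4 of 22 higher and 1 lower), senescence genes with cyclin-dependent kinase inhibitors (adjusted p = 0.0792; 3 of 13 higher and 1 lower), MHC class I (adjusted p = 0.104; 1 of 14 higher), extracellular matrix (adjusted p = 0.852; 7 of 31 higher and 5 lower) and fibroblast markers (adjusted p = 0.965; 2 of 6 higher and 1 lower). The medians of the matrix and fibroblast lists were -0.005 and -0.090, while their means were 0.041 and 0.107.

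**Figure D3:**
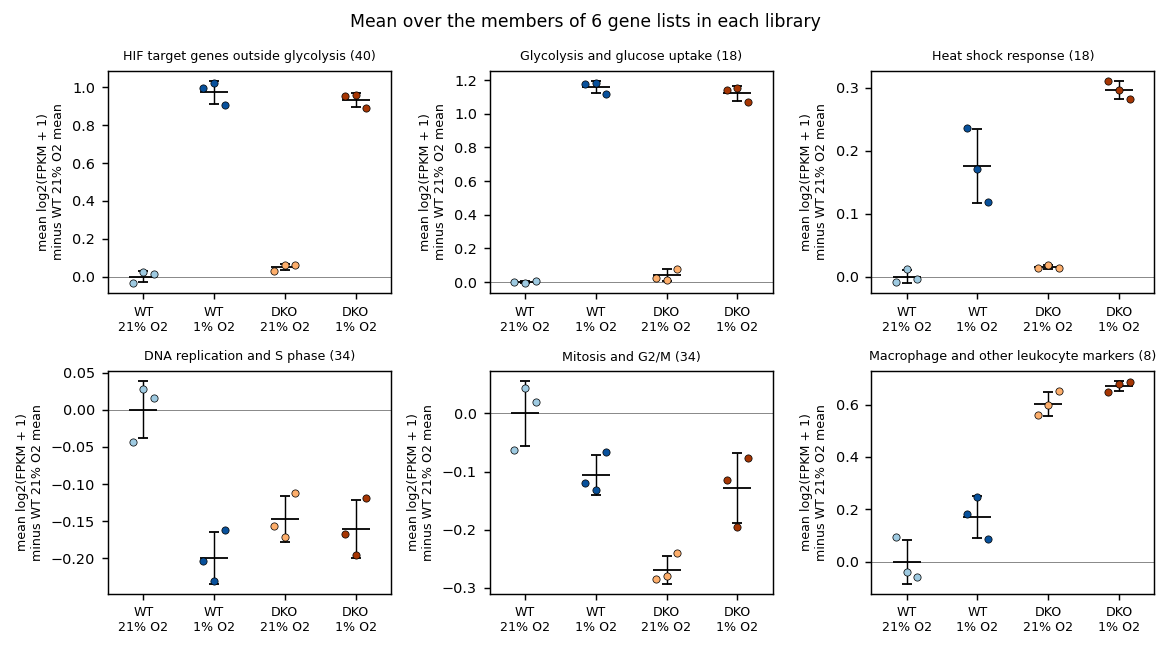
Mean of log2(FPKM + 1) over the tested members of 6 lists in each library (points), as the distance from the mean of the wild type normoxia libraries, with the mean and SD of 3 libraries. The mitosis mean is -0.269 in double knockout normoxia and -0.129 in double knockout hypoxia, and the leukocyte mean is 0.603 and 0.671.

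In normoxia 929 genes differed between genotypes (8.2%; limma adjusted p under 0.05), 437 higher and 492 lower in the double knockout, of which 16 and 6 differed by more than 1 on the log2 scale. The count was 616 with the libraries of this comparison alone, 583 without wild type normoxia library 2 and 617 without double knockout normoxia library 2. Testing each transcript gave 583 transcripts.

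Genes near Map3k10 were called more often than genes elsewhere. Within 10 Mb of it 42 of 196 tested genes were called in normoxia (21.4%), against 775 of 10035 on chromosomes without a targeted gene (7.7%; Fisher's exact odds ratio 3.26, p = 2.27e-09). In hypoxia 66 of 196 were called (33.7%), against 1556 of 10035 (15.5%; Fisher's exact odds ratio 2.77, p = 5.47e-10). Apoe, Blvrb, Mrps12 and Zfp93 lie in this stretch, and Pop4 just outside it. Within 10 Mb of Map3k11 the shares were 10 of 185 (5.4%; Fisher's exact odds ratio 0.683, p = 0.327) and 21 of 185 (11.4%; 0.698, p = 0.1495). For both loci together the odds ratios were 1.89 (Fisher's exact p = 9.83e-05) and 1.61 (p = 0.000244), and against the rest of chromosomes 7 and 19 they were 1.38 (Fisher's exact p = 0.0975) and 1.19 (p = 0.254).

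**Figure D4:**
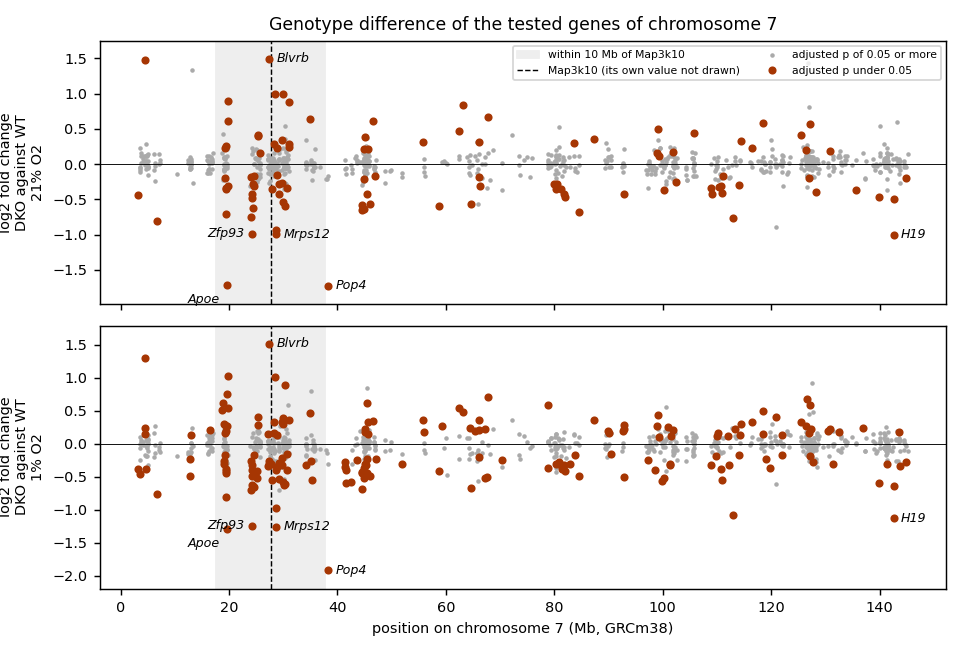
Each point is a tested gene of chromosome 7 at its position in Mb (GRCm38), with the log2 fold change of double knockout against wild type in normoxia (top) and hypoxia (bottom) on the y axis. The grey band spans 10 Mb on each side of Map3k10, where 42 of 196 genes were called in normoxia and 66 in hypoxia.

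Under hypoxia, the genotypes differed in many of the genes that set them apart in normoxia. Clca2 was at 49.8 ± 1.45 FPKM in the double knockout against 15.97 ± 0.745 in wild type (SD, n = 3, limma log2 fold change 1.58, adjusted p = 2.10e-08). Lcn2, a secreted iron-binding protein of inflammation, was at 19.9 ± 2.60 against 6.56 ± 1.86 FPKM (SD, n = 3, limma log2 fold change 1.49, adjusted p = 9.51e-05). Hey1, an effector of Notch in arterial endothelium, was at 1.07 ± 0.243 against 4.73 ± 1.40 FPKM (SD, n = 3, limma log2 fold change -1.44, adjusted p = 0.000116). Ednrb, the endothelin receptor that clears its ligand, was at 12.7 ± 2.02 against 29.2 ± 4.598 FPKM (SD, n = 3, limma log2 fold change -1.13, adjusted p = 8.09e-05). The neuropeptide Nts was at 18.5 ± 2.53 against 46.4 ± 1.98 FPKM (SD, n = 3, limma log2 fold change -1.29, adjusted p = 1.37e-06).

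Blvrb (1.52), Col15a1 (1.35), Prg2 (1.32), Lyz2 (1.25) and C3 (1.25) were among the larger increases as log2 fold changes, and Pop4 (-1.92), Fhl1 (-1.66), Apoe (-1.29) and Mrps12 (-1.26) among the larger decreases. Among the HIF and glycolysis genes, Hilpda, which guards lipid droplets, was lower in double knockout hypoxia at 30.9 ± 4.78 against 49.6 ± 3.54 FPKM (n = 3), and Hk2, the first enzyme of glycolysis, at 10.5 ± 1.06 against 19.2 ± 2.54 FPKM. The difference between the genotypes' responses did not pass for Hilpda (limma log2 difference -0.69, adjusted p = 0.0780) or Hk2 (-0.41, adjusted p = 0.181). Cxcr4, a chemokine receptor of tip cells, was higher at 283.9 ± 6.77 against 191.8 ± 12.6 FPKM, and Cldn5, which seals endothelial junctions, was lower at 199.6 ± 15.6 against 293.5 ± 29.5 FPKM (n = 3). All 3 double knockout libraries lay on 1 side of all 3 wild type libraries for these genes.

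Of 20 p53 targets, 10 were higher, 1 was lower and 9 did not pass (10 and 1 adjusted over the list alone; limma camera adjusted p = 0.000249; adjusted p = 0.118 with an estimated correlation). Among them Cdkn1a was at 98.5 ± 2.35 against 77.6 ± 1.62 FPKM (n = 3), Mdm2, which degrades p53, at 170.1 ± 2.56 against 143.6 ± 5.10 FPKM, and Ccng1 at 227.8 ± 2.54 against 191.6 ± 2.14 FPKM. Heat shock genes had 6 of 18 higher and 1 lower (6 and 1 adjusted over the list alone; limma camera adjusted p = 0.00737; adjusted p = 0.337 with an estimated correlation), with Hspa1a (0.65) and Hspa4 (0.14) among the higher ones. Lymphatic endothelial markers had 4 of 10 lower and 1 higher (6 and 1 adjusted over the list alone; limma camera adjusted p = 0.0276; adjusted p = 0.828 with an estimated correlation), with the hyaluronan receptor Lyve1 at 264.9 ± 14.3 against 390.3 ± 27.2 FPKM, and fry did not call this list (limma adjusted p = 0.0726). Leukocyte markers had 3 of 8 higher (3 adjusted over the list alone; limma camera adjusted p = 0.00316; adjusted p = 0.118 with an estimated correlation). Smooth muscle and pericyte markers had 3 of 7 higher and 1 lower (4 and 1 adjusted over the list alone). Fry called them and camera did not (limma camera adjusted p = 0.151, 0.828 with an estimated correlation, and fry adjusted p = 0.0294). Their mean was 0.493, 0.444 and 0.422 in the double knockout hypoxia libraries against 0.343, 0.267 and 0.156 in wild type hypoxia, from the same origin as in normoxia.

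The MLK family list was lower (limma camera adjusted p = 0.0118; adjusted p = 0.337 with an estimated correlation), a call that ended without a filter on low values and with the libraries of this comparison alone (limma camera adjusted p = 0.105 and 0.0676). Mitosis genes were not called in hypoxia (limma camera adjusted p = 0.649), with 1 of 34 lower. Other lists not called by limma's camera were interferon-stimulated genes (adjusted p = 0.548; 1 of 31 higher and 1 lower), nuclear genes of oxidative phosphorylation (adjusted p = 0.151; 1 of 41 higher), junction genes (adjusted p = 0.575; 4 of 22 higher and 4 lower), markers of lung capillary, arterial and venous endothelium (adjusted p = 0.903; 6 of 17 higher and 6 lower) and lung epithelial markers (adjusted p = 0.657; 1 of 7 higher and 1 lower). The junction, capillary and epithelial lists had medians of 0.034, 0.037 and 0.086 and means of -0.022, -0.068 and -0.002.

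In hypoxia 1832 genes differed between genotypes (16.1%; limma adjusted p under 0.05), 874 higher and 958 lower in the double knockout, with 18 in each direction past 1 on the log2 scale. The count was 1175 without wild type hypoxia library 2 and 1185 without double knockout hypoxia library 1. The genotype differences in normoxia and in hypoxia share no library: 271 genes were higher in both and 267 lower in both, against 33.6 and 41.4 if the calls were independent, and 5 were called in opposite directions. Across genes their log2 fold changes correlated with Pearson r = 0.529 and Spearman rho = 0.362.

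The hypoxia response itself differed between genotypes for 22 genes past the threshold in limma, with 1820 of 11378 at an unadjusted p under 0.05. Kcnj2, an inward rectifier potassium channel, was at 0.851 ± 0.0147 and 1.08 ± 0.0924 FPKM in wild type normoxia and hypoxia and at 1.35 ± 0.181 and 3.26 ± 0.126 in the double knockout (SD, n = 3, limma log2 difference 0.69, adjusted p = 0.0347). The ETS factor Etv4 was at 16.9 ± 0.202 and 18.4 ± 0.149 FPKM in wild type and at 14.1 ± 0.459 and 20.3 ± 0.749 in the double knockout (SD, n = 3, limma log2 difference 0.38, adjusted p = 0.0347). Ackr3, a scavenging chemokine receptor, was at 1.94 ± 0.0163 and 2.07 ± 0.126 FPKM in wild type and at 2.44 ± 0.562 and 0.787 ± 0.164 in the double knockout (SD, n = 3, limma log2 difference -0.99, adjusted p = 0.0354). The tRNA methyltransferase Trmt5 was at 6.31 ± 0.5999 and 4.59 ± 0.380 FPKM in wild type and at 7.39 ± 0.311 and 2.97 ± 0.104 in the double knockout (SD, n = 3, limma log2 difference -0.69, adjusted p = 0.0347). Dusp5, a nuclear phosphatase of ERK, was at 11.9 ± 0.472 and 13.5 ± 0.711 FPKM in wild type and at 12.6 ± 0.611 and 9.99 ± 0.176 in the double knockout (SD, n = 3, limma log2 difference -0.47, adjusted p = 0.0347).

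**Figure D5:**
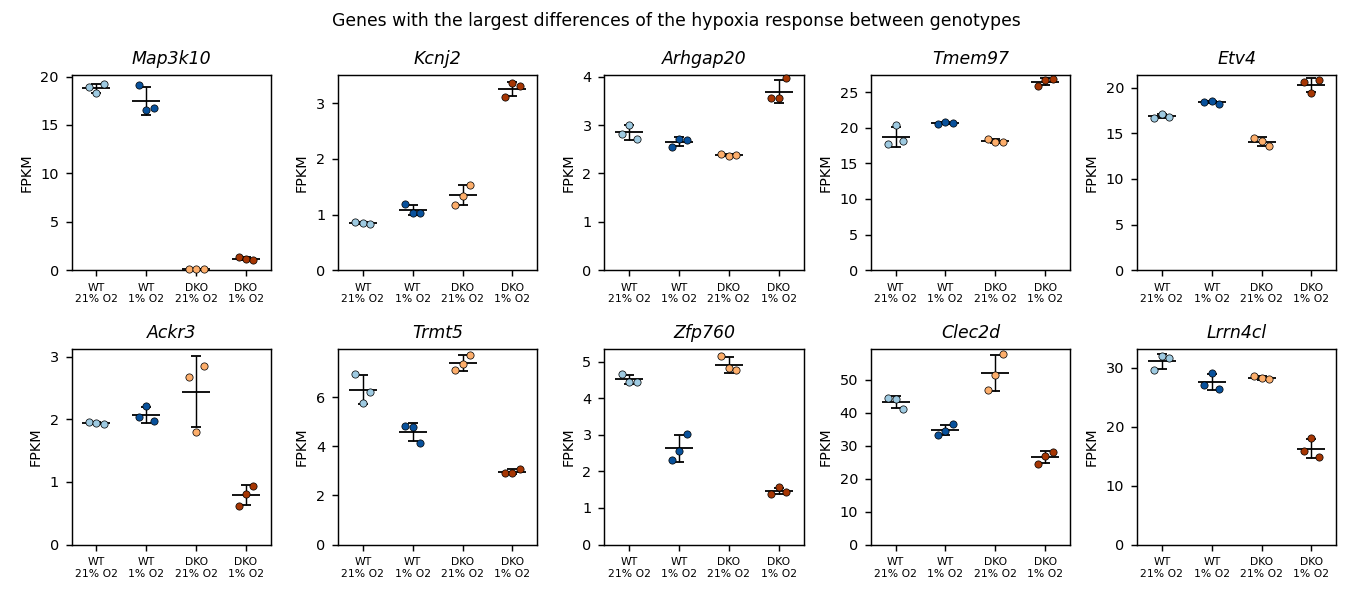
FPKM in each library (points) of the 4 groups, with the mean and SD of 3 libraries, for the 5 named genes with the largest positive and the 5 with the largest negative difference of the hypoxia response. Kcnj2 reaches 3.26 FPKM in double knockout hypoxia, and Ackr3 is at 0.787 FPKM there.

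Arhgap20 (0.54), Tmem97 (0.39), Lrrn4cl (-0.60), Clec2d (-0.63) and Zfp760 (-0.66) also differed in response. Apart from Map3k10, whose difference passed in all 19 alternatives run for named genes, each of these genes lost its call in 11 to 16 of them. These 19 do not include each transcript on its own, where no transcript passed. Among the lists, mitosis genes responded more positively in the double knockout (mean log2 difference 0.245; limma camera adjusted p = 1.35e-14; adjusted p = 0.269 with an estimated correlation), though no single member passed (20 higher adjusted over the list alone). S phase genes also responded more positively (0.185; limma camera adjusted p = 1.10e-08; adjusted p = 0.269 with an estimated correlation), with 12 of 34 higher adjusted over the list alone, as did heat shock genes (0.107; limma camera adjusted p = 0.00265; adjusted p = 0.269 with an estimated correlation), with 3 of 18. HIF targets outside glycolysis responded less (-0.090; limma camera adjusted p = 0.0425; adjusted p = 0.684 with an estimated correlation), with 2 higher and 7 lower adjusted over the list alone, a call that ended with a pseudocount of 0.1 and with fry (limma adjusted p = 0.0544 and 0.275). Glycolysis genes were not called (limma camera adjusted p = 0.220).

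Of the 22 genes past the threshold (limma adjusted p under 0.05), 8 had a more positive and 14 a more negative response in the double knockout. The count was 4, 1 and 1 without wild type normoxia library 1, 2 or 3, and 39 and 2 without wild type hypoxia library 1 or 2. It was 2, 2 and 1 without double knockout normoxia library 1, 2 or 3, and 2 and 1 without double knockout hypoxia library 1 or 3. Array weights gave 153 genes, no trend in the variance gave 6, and quantile normalization gave 12. Tested singly in limma, 0 of 18090 transcripts passed, with 2168 at an unadjusted p under 0.05.

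Averaged over genotypes, hypoxia changed 5193 genes (45.6%; limma adjusted p under 0.05), 2585 higher and 2608 lower. Of 36 lists 14 were called by limma's camera, and 12 of these calls were lost with an estimated correlation. The HIF and glycolysis lists kept theirs (limma camera adjusted p = 0.0315 and 0.0259). Quantile normalization ended 8 of the 14 calls.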

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

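The tests of poorer mapping, of kinase loss acting anywhere and of all leukocyte markers were chosen after the results were seen, as were the reading of the correlation near Map3k10 against windows with as many calls, the slopes of gene subsets, the second form of the library exchange and the look at which exchange came highest. The odds ratios near the targeted genes had been seen before any prediction about that stretch was written.

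A difference between the genotypes' hypoxia responses, tested as an interaction in limma, singled out 22 genes. The named ones with a more positive response in the double knockout were Map3k10 (1.018), Kcnj2 (0.692), Arhgap20 (0.544), Tmem97 (0.385) and Etv4 (0.379). Those with a more negative response were Ackr3 (-0.995), Trmt5 (-0.694), Zfp760 (-0.656), Clec2d (-0.633), Lrrn4cl (-0.599) and Dusp5 (-0.472). The same test over lists singled out mitosis (0.245), S phase (0.185), heat shock (0.107) and HIF targets outside glycolysis (-0.090), as mean log2 differences. None of these list calls held with an estimated correlation between genes (limma camera adjusted p = 0.269 for the first 3 lists and 0.684 for HIF targets, the highest over the alternatives run for each list). The Map3k10 difference concerns a gene whose main transcript is at 0 in the double knockout, and its remaining transcript rose by about as many FPKM in wild type (0.990) as in the double knockout (1.02). On a log scale the same rise weighs more from a low base.

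More genes near Map3k10 differed between genotypes than elsewhere. The share called in normoxia, 21.4%, exceeded the highest share (13.3%) among 660 windows of 196 genes on other chromosomes. These windows overlapped, so they are not 660 separate comparisons. The excess argues against kinase loss acting on genes anywhere as the whole cause. Poorer mapping of reads from kept DNA, as the whole cause, would lower nearly all of these genes. Of the called genes 59.5% were lower in normoxia (exact 95% interval 43.3 to 74.4%) and 63.6% in hypoxia (50.9 to 75.1%). That argues against mapping as the whole cause but does not exclude a part played by it. The genotype effects in normoxia and hypoxia correlated near the gene at r = 0.827 (highest window 0.773), but a stretch with more called genes has a higher r whatever the cause, and no window elsewhere held as many, so this test does not decide on DNA of another strain kept beside the Map3k10 allele. Such DNA and an untested effect of Map3k10 loss on its neighbours both stay open. The changes of Apoe, Blvrb, Mrps12 and Zfp93, and of Pop4 just outside the stretch, thus cannot be assigned to kinase loss. The rest of chromosomes 7 and 19 had 10.3% of genes called in normoxia and 19.9% in hypoxia, against 7.7% and 15.5% on other chromosomes. The strain of origin of such DNA and the background of the double knockout are not given in the sources used here. Genotype differences elsewhere, that of Erdr1 included, thus cannot be assigned to kinase loss alone either.

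Of 8 tested leukocyte markers 4 were higher in the double knockout in normoxia and 3 in hypoxia, and the list call in hypoxia was lost with an estimated correlation (limma camera adjusted p = 0.118, the highest over the alternatives) and kept in normoxia (adjusted p = 0.0335, the highest there). Of 14 detected alveolar macrophage markers 10 were higher at both oxygen levels (71.4%), and of 23 detected leukocyte markers 15 were (65.2%), between the bounds set for and against more such cells, with 4 genes in both lists. Marco was at 0.425 and 0.504 FPKM in wild type and 1.99 and 2.36 in the double knockout, and Lyz2 at 21.4 and 24.5 against 62.1 and 59.6 FPKM, while Ear1 and Pparg were not higher at both levels. Pparg, Mrc1 and Olr1 are also expressed by endothelium. More macrophages in the double knockout cultures and expression of these genes by the endothelial cells themselves both stay open.

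The response to hypoxia had a larger amplitude in the double knockout, with a slope of 1.37 over all tested genes and 1.26 over those with a mean of at least 20 FPKM. Of 200 exchanges of genotype among libraries within each oxygen level, 2 gave a slope as far from 1, the real one included. The highest other also reached 1.37 (median 1.115), and it kept the hypoxia libraries of each genotype together while mixing the normoxia libraries. With the mean genotype effect taken off first, 1 of 200 gave a slope as far from 1 (highest other 1.365). These shares argue against chance assignment but do not exclude it, as other exchanges came as far or nearly as far from 1. The slope was 1.346 with sampling variance taken off, which argues against a larger spread among the double knockout libraries, and 1.359 with the trend on GC content and length removed (1.21 to 1.45 without 1 library), which argues against that bias. It was 0.968 for HIF and glycolysis genes, and an effect of the kinases on the rest of the response stays open, as does any unrecorded difference in handling of the hypoxia libraries.

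For the comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. The real splits called 2370, 4468, 929 and 1832 genes, each the 1 split with as many, and the highest others called 1, 1, 0 and 1 in limma. For the average over genotypes, 1 of 100 exchanges of oxygen level called as many as the real 5193 genes (highest other 3304), so chance can be excluded. For the difference of responses, 1 of 100 exchanges of genotype called as many as the real 22 (highest other 1). In this fit, the exchanges argue against chance assignment of these libraries for the count, but not for each of the genes. Leaving out 1 library moved that count between 1 and 39. The exchanges take the libraries as independent, which the labels do not state. The exchange test of the difference was run in 2 forms, and the result of 1 form is given here. Without the variance trend the real grouping called 6 genes, and with a replicate block it called 1. No exchanges are given for those fits, so chance is not excluded for the count under them.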

How the results depend on the processing

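Removal of the trend on GC content and length and omission of chromosomes 7 and 19 were chosen after seeing the data. Of 9439 results of named genes under the alternatives, 8792 kept direction and call and 647 lost the call. Of 522 results of called lists, 446 kept it and 76 lost it, 47 of these with an estimated correlation between genes and 17 with quantile normalization. None reversed.

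For the genotype difference in normoxia (929 genes), the libraries of the comparison alone gave 616 and each transcript on its own 583. For the difference of responses (22 genes, 8 higher and 14 lower), quantile normalization gave 12 (6 and 6), no variance trend 6 (4 and 2), array weights 153 (63 and 90) and single transcripts 0 in limma, with 2168 at an unadjusted p under 0.05. No filter gave 19 (11 and 8), and removal of the trend on GC content and length gave 21 (11 and 10). Which direction held more calls depended on the scaling. Equal library medians gave 518 higher and 435 lower for the genotype in normoxia (437 and 492 without it) and 1034 and 858 in hypoxia (874 and 958 without it). They gave 1382 and 1065 for hypoxia in wild type, 2454 and 2128 in the double knockout and 2885 and 2419 for the average. Quantile normalization gave 1088 and 1258, 2119 and 2293, and 2384 and 2747 for these 3, and 850 and 838 for the genotype in hypoxia. Removal of the GC content and length trend gave 1126 and 915 for the genotype in hypoxia. The correlation between the hypoxia responses was 0.781 over genes with at least 5 FPKM. The cause was not tested.

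Leaving out 1 library gave 1382 to 2351 genes for hypoxia in wild type, with 1382 without wild type hypoxia library 1 and 1495 without library 2. It gave 583 to 806 for the genotype in normoxia, with 583 without wild type normoxia library 2 and 617 without double knockout normoxia library 2. For the genotype in hypoxia it gave 1175 to 1425, with 1175 without wild type hypoxia library 2 and 1185 without double knockout hypoxia library 1. The correlation between the responses was 0.690 to 0.731. The difference of responses gave 1 to 39 genes. It was 4, 1 and 1 without wild type normoxia library 1, 2 or 3, 39 and 2 without wild type hypoxia library 1 or 2, 2, 2 and 1 without double knockout normoxia library 1, 2 or 3, and 2 and 1 without double knockout hypoxia library 1 or 3. Hypoxia in the double knockout (3692 to 4112) and the average (4618 to 5146) stayed within 1.5 times.

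A replicate block gave 1 gene for the difference of responses and moved no other count by over 1.5 times. No pairing by number was visible: of 18 pairs with the same number 1 had a correlation of deviations above 0.1 (median 0.009), and 5 of 12 libraries correlated best with their own number. That does not show that libraries with the same number came from separate preparations, which the labels leave open.

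At the estimated depth, genes under 1 FPKM, such as Map3k9, were not tested, and the log2 fold changes of genes near that level are understated.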

Other observations

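The grouping of arterial and Notch-related genes below was chosen after their values were seen. Hey1 rose with hypoxia in wild type from 1.43 ± 0.171 to 4.73 ± 1.40 FPKM (SD, n = 3, limma log2 fold change 1.21, adjusted p = 0.000415) and did not pass in the double knockout (limma log2 fold change 0.15, adjusted p = 0.493), where it went from 0.864 ± 0.133 to 1.07 ± 0.243 FPKM. Klf2, a transcription factor of endothelium under flow, rose in wild type from 3.15 to 5.67 FPKM (limma log2 fold change 0.66, adjusted p = 0.00362) and did not pass in the double knockout (-0.05, adjusted p = 0.768). Gja4, a connexin of arterial endothelium, rose in wild type (limma log2 fold change 0.65, adjusted p = 0.00298) and did not pass in the double knockout (-0.06, adjusted p = 0.710). The difference between genotypes did not pass for any of them in limma (adjusted p = 0.0780 for Hey1, 0.0971 for Klf2 and 0.0863 for Gja4), so a difference in response is not shown.

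Nnt, whose gene is partly deleted in the C57BL/6J substrain, had means of 13.3 and 12.3 FPKM in wild type and 13.1 and 12.0 FPKM in the double knockout, in normoxia and hypoxia. The mitochondrial gene mt-Nd4l was listed at 0 in all 3 wild type normoxia libraries and at 1.25, 2.70 and 2.17 FPKM in wild type hypoxia. It was at 1.60, 1.34 and 4.93 FPKM in double knockout normoxia and at 4.07, 1.44 and 4.04 FPKM in double knockout hypoxia.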
